A study of Mus musculus with 40 samples.

How the data were processed

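Total RNA (Trizol, then RNeasy) from the prefrontal cortex and the hippocampus of male Df(16)A/+ mice and wild-type littermates was labelled with biotin and hybridized to Affymetrix Mouse430_2 arrays, 10 arrays per genotype and region and 40 in all, with 45101 probe sets each. The deposited values are log2 GCRMA signals per the submitters' processing notes. The GCRMA version, its settings and the arrays normalized together are not given in the sources used here. Array values were nearly equal in distribution within a region and apart between regions: the 95th percentile was 11.6 to 11.7 in the prefrontal cortex and 10.9 to 11.1 in the hippocampus, and the maxima were 16.0 to 16.2 and 15.2 to 15.5. Each region was therefore analysed on its own, and the planned comparison of the regions in wild type was not run. The deposited text records of each array run were used for batches alone (hybridization run 1 to 5, chip lot 1 to 5, hybridization day and fluidics station), and 2 arrays lacked a scan record.

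Probe sets were assigned to genes with the annotation supplied for the array: 34945 matched 1 gene, 932 several and 9160 none, and 64 control probe sets were left out. Gene names and the genes whose span holds an annotated microRNA came from the gene annotation of assembly GRCm38.p6, and 226 such genes were found for 522 microRNA genes, 169 of them on the array. Probe sets above 4 (log2) in at least 10 arrays of a comparison were tested. Where a single value per gene was needed, the probe set with the highest mean over the arrays in the fit was used.

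Groups were taken from the sample titles. Each genotype comparison was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 10 against 10 arrays, two-sided, no covariate) and adjusted by Benjamini-Hochberg at 0.05. The interaction of genotype and region was a contrast of 4 group means over all 40 arrays, for which a constant offset between separately normalized regions cancels. A difference of scale would not cancel. The regions did not differ by a constant, since array medians overlapped (3.68 to 3.88 and 3.55 to 3.94) while the 95th percentiles and maxima did not. Sharing between regions was counted as probe sets called in both in the same direction, against the product of the counts, and as the correlation of the log2 differences. Of 33 gene lists, 16 of them markers of cell types or brain regions, those with at least 3 measured genes were tested with camera (limma) at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison, with the estimated correlation and fry as checks. The blood and the olfactory bulb lists had fewer than 3 measured genes and were not tested. The R packages data.table (version 1.17.8) and statmod (version 1.5.0) were used for tables and for correlated blocks.

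The comparisons, tests, gene lists, named-gene rule and the alternatives listed next were set before the data were examined. Named genes were every measured interval gene, the 10 largest rises and the 10 largest falls among called genes outside the interval, the 4 members with the smallest p of each list that passed or had a called member, the genes studied downstream of this deletion, called members of the microRNA lists, and the 10 genes with the smallest adjusted p in the interaction. The alternatives were no filter, a filter above 6, quantile normalization, centring each array on its median, an intensity trend with robust variance, array weights, Welch's test, 1 fit of all 40 arrays, the replicate number as a block, the animal by number as a random or fixed block, hybridization day, chip lot and fluidics station as blocks, a 1.5-fold threshold, other choices of probe set per gene, and leaving out each array in turn. After the data were seen, the hybridization run as a block, run and lot together, single runs or lots alone, and the difference of the beta-actin 3' and 5' probe sets as a covariate were added. The hybridization day could not be a block in the hippocampus, where all arrays shared 1 day.

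The number of arrays limits the precision. The fit was tested on simulated data of the same size and spread: differences of 0.25, 0.5 and 1 (log2) were recovered for 47.8%, 92.5% and 98.5% of changed probe sets in the prefrontal cortex, with 5.4% false calls, and for 29.9%, 85.1% and 100% in the hippocampus, with 3.4% false calls. The simulated noise was independent between probe sets and held no run or lot effect, so these rates do not cover batch effects in the real arrays. For each count, 100 splits of the arrays into groups of equal size, the real one included, were fitted the same way (seed 1). Genes whose span holds a microRNA were compared with 10000 random lists drawn from the 20 nearest in mean value. No coordinates are given, since the build of the array annotation is not given in the sources used here.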

Results

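The measurements were 40 expression arrays (Affymetrix Mouse430_2), 1 per tissue sample. The mice were males 8 weeks old on the C57BL/6 background. Df(16)A/+ mice carry a heterozygous deletion on chromosome 16 that covers the mouse counterparts of the genes lost in the human 22q11.2 deletion, and wild-type littermates were the controls. The prefrontal cortex and the hippocampus were each profiled in 10 Df(16)A/+ and 10 wild-type samples, so every group mean below rests on n = 10 arrays. Values are GCRMA signals on the log2 scale, and the number of arrays sets the precision. In the prefrontal cortex 21653 probe sets for 10991 named genes passed the filter on low values, and in the hippocampus 21153 probe sets for 10822 named genes. Differences are Df(16)A/+ minus wild type throughout, with the standard error (SE) of the fitted log2 difference or the standard deviation (SD) between arrays. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05.

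Which genes of the deleted interval lost expression was asked first, since these genes also check the genotype labels. All 19 measured interval genes were lower in the prefrontal cortex of Df(16)A/+ mice and 18 of 19 were lower in the hippocampus, with the same counts when adjusted over the list alone. The median interval gene had a log2 difference of -1.23 in the prefrontal cortex, which left 42.7% of the wild-type signal, and -1.06 in the hippocampus, which left 48.1%. By the mean over the interval genes, the 10 Df(16)A/+ prefrontal arrays lay between -1.24 and -1.06 around the wild-type mean and the wild-type arrays between -0.10 and 0.10. The corresponding hippocampal ranges were -1.09 to -0.89 and -0.12 to 0.07, so no array stood on the side of the other genotype.

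Dgcr8, whose product works with Drosha to process primary microRNA transcripts, was among the less reduced genes. Its signal fell from 8.96 ± 0.13 to 8.23 ± 0.25 (SD, log2) in the prefrontal cortex, 60.3% of wild type (log2 difference -0.73 ± 0.09 SE, adjusted p = 1.5e-05), and to 61.9% in the hippocampus (-0.69 ± 0.08 SE, adjusted p = 3.2e-05). Another Dgcr8 probe set had log2 differences of -0.913 (adjusted p = 7.2e-09) in the prefrontal cortex and -0.605 (adjusted p = 1.3e-05) in the hippocampus. Prodh, the mitochondrial proline dehydrogenase, was at 51.1% and 45.0% of wild type in the prefrontal cortex and hippocampus. Zdhhc8, a palmitoyltransferase, was at 39.0% and 48.5%. Rtn4r, the Nogo receptor, was at 48.4% and 46.8%, and Slc25a1, the mitochondrial citrate carrier, at 42.5% and 43.6%. Cldn5, a tight-junction protein of brain endothelium, had the lowest remaining signal in both regions by the probe set used per gene, 32.5% and 39.9%, while another Dgcr6 probe set had log2 differences of -1.78 and -1.77, lower than that of Cldn5. Mrpl40, a mitochondrial ribosomal protein, was at 36.6% and 42.1%. The other measured genes, Dgcr2, Dgcr6, Ess2, Ranbp1, Trmt2a, Tango2, Arvcf, Gp1bb, Ufd1, 2510002D24Rik and Hira, had between 38.8% (Trmt2a) and 50% (Hira) of the wild-type signal in the prefrontal cortex and between 40.3% (Dgcr6) and 59.5% (Ess2) in the hippocampus. By the probe set used per gene, Txnrd2, the mitochondrial thioredoxin reductase, was the exception. It was at 78.4% in the prefrontal cortex (adjusted p = 0.012) and 95.6% in the hippocampus (log2 difference -0.06 ± 0.06 SE, adjusted p = 0.55). Its probe sets differed, since another Txnrd2 probe set fell by 0.99 in the prefrontal cortex (adjusted p = 1.9e-06) and by 0.85 in the hippocampus (adjusted p = 0.00076). The hippocampal Df(16)A/+ mean of that probe set, 3.86, lay under the filter value of 4, so that the size there is uncertain. Another Trmt2a probe set had smaller log2 differences than the one used, -0.38 in the prefrontal cortex and -0.49 in the hippocampus. So did a Dgcr2 probe set in the hippocampus (-0.38), where its Df(16)A/+ mean of 3.97 lay under the filter value. With the hybridization run as a block, 18 of 19 genes in the prefrontal cortex and 14 of 19 in the hippocampus passed, with medians of -1.22 and -1.04.

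**Figure D1:**
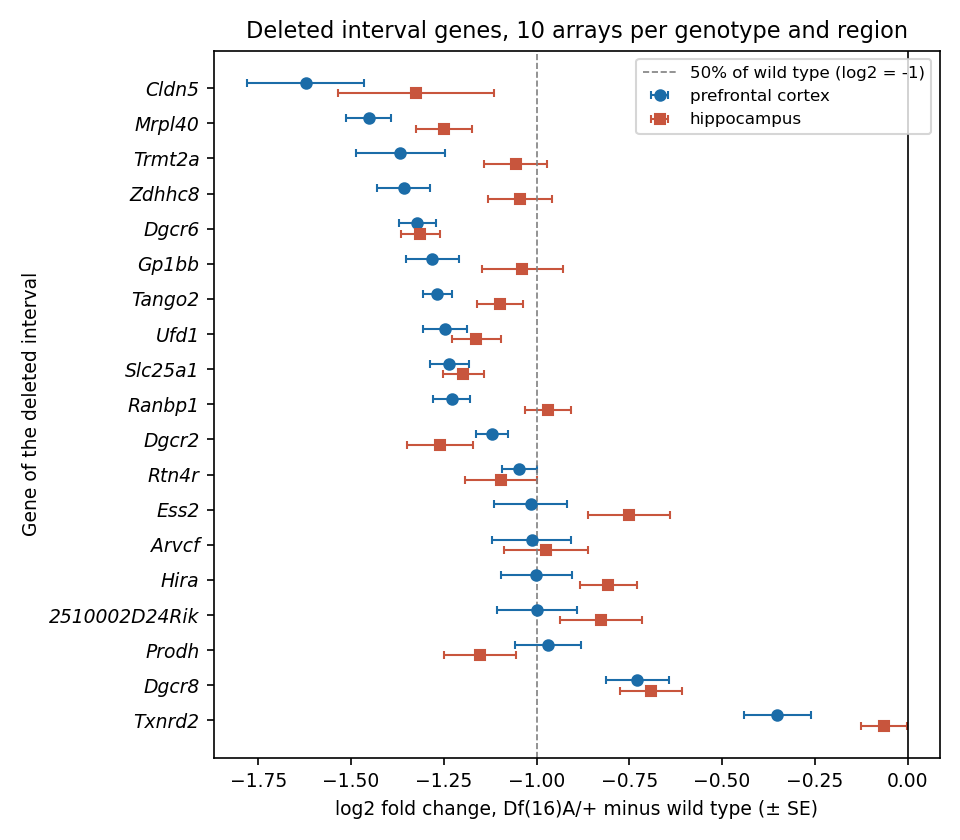
Log2 fold change (x axis, Df(16)A/+ minus wild type, with SE bars) of each measured gene of the deleted interval (y axis) in prefrontal cortex (circles) and hippocampus (squares), 10 arrays per genotype and region. The dashed line marks 50% of wild type, and Txnrd2 in the hippocampus is the 1 value whose difference did not pass the test.

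The prefrontal comparison asked which genes outside the deletion differ between the genotypes. Noncoding primary microRNA transcripts stood out: of 16 measured, 9 rose in Df(16)A/+ mice and none fell (10 rose when adjusted over the list alone). This did not hold for protein-coding genes whose span holds a microRNA. Of 120 measured outside the interval, 5 rose and 10 fell, with a median of -0.02 (log2). Lncppara rose 2.33-fold, from 6.56 ± 0.15 to 7.77 ± 0.25 (SD, log2), and A330023F24Rik 2.05-fold, from 8.99 ± 0.23 to 10.03 ± 0.07. Emc10, a subunit of the endoplasmic reticulum membrane protein complex, rose 1.45-fold, and Fos and Npas4, transcription factors induced by neuronal activity, fell to 53.4% and 49.8% of wild type. Genes for the mitochondrial respiratory chain and the mitochondrial ribosome were lower by small amounts, with list medians of -0.12 and -0.14 on the log2 scale (adjusted p = 0.25 and 0.27 with an estimated correlation, which did not pass).

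Over all probe sets, limma called 4000 of 21653 in the prefrontal cortex (18.5%), 1286 higher and 2714 lower, of which 3972 lay outside the interval genes. The share of higher calls was 32.1% as deposited, 42.8% after quantile normalization and 24.1% after median centring. The median size of a called difference was 0.21 on the log2 scale, and 232 differences reached 1.5-fold, 177 of them higher. At an unadjusted p under 0.05 the count was 7158. With 1 probe set per gene, 359 genes were higher and 1725 lower.

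The primary microRNA transcripts rose as a list (camera, adjusted p = 3.2e-18, and 1.2e-06 with an estimated correlation). Their mean over the list was 0.39 ± 0.03 (SD) above the wild-type mean, and the 10 Df(16)A/+ arrays, at 0.34 to 0.43, lay above all 10 wild-type arrays, at -0.15 to 0.09. Besides Lncppara (adjusted p = 5.9e-09) and A330023F24Rik (adjusted p = 6.2e-09), C130071C03Rik rose 1.47-fold (adjusted p = 2.2e-07), Mir22hg 1.43-fold (adjusted p = 4.5e-08), Mir9-3hg 1.39-fold (adjusted p = 3.4e-08), Dleu2 1.55-fold, Ftx 1.48-fold, Mirg 1.27-fold and Mir124-2hg 1.14-fold (adjusted p = 0.020). Each of these 9 was higher than the wild-type mean in 10 of 10 Df(16)A/+ arrays. Of 21 proteins of the microRNA pathway, Tnrc6b rose (0.15 ± 0.04 SE) and Prkra, a Dicer partner, fell (-0.31 ± 0.07 SE), and the list did not pass (adjusted p = 0.18), though it passed upward with the lot block (adjusted p = 0.049) and with run and lot blocks (adjusted p = 0.0085, median 0.06). Higher primary microRNA transcripts have been described in this mutant line before, so the list is not independent of earlier work.

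Of 3 measured genes studied downstream of this deletion, 2 rose, the same number when adjusted over the list alone: Emc10 (0.54 ± 0.05 SE, adjusted p = 1.4e-06) and Gsk3b, a kinase of the Wnt pathway (0.27 ± 0.06 SE, adjusted p = 0.0027). Atp2a2, a calcium pump of the endoplasmic reticulum, had a difference of 0.05 ± 0.04 SE (adjusted p = 0.30). This list passed (adjusted p = 5.4e-05, and 0.010 with an estimated correlation), but it was drawn from work on this line and is not independent evidence of its direction.

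Among 42 genes of the glutamatergic synapse, 10 rose and 1 fell (11 and 1 when adjusted over the list alone). Dlg4, the scaffold PSD-95, rose by 0.49 ± 0.09 SE, Dlgap2 by 0.38 ± 0.08, the vesicular glutamate transporter Slc17a7 by 0.32 ± 0.06 and the AMPA receptor subunit Gria1 by 0.27 ± 0.04. The list passed (adjusted p = 9.1e-06, and 0.010 with an estimated correlation), with a median of 0.03 and a mean of 0.07. The number of higher genes was 7 with the run block, 4 with the lot block, 0 with both and 6 after median centring. Of 76 genes of oxidative phosphorylation 49 fell and none rose (56 fell when adjusted over the list alone), among them Cyc1 (82.3% of wild type), Atp5c1 (86.7%), Ndufs3 (89.0%) and Cox5b (89.7%). Of 74 mitochondrial ribosomal proteins outside the interval 39 fell and none rose, against 54 lower and 2 higher when adjusted over the list alone. Mrps11 was at 75.0% of wild type, Mrpl57 at 83.0%, Mrps12 at 85.3% and Mrpl41 at 86.0%. Cytosolic ribosomal proteins fell in 13 of 45 cases (23 when adjusted over the list alone), with Rps4l at 69.9% and Rpl22l1 at 87.2%. These lists passed with the preset correlation, at adjusted p = 1.0e-12, 6.2e-10 and 9.9e-05, but not with an estimated correlation, at adjusted p = 0.25, 0.27 and 0.53. The numbers of lower genes became 29, 23 and 6 with the run block, 13, 13 and 1 with the lot block and 2, 2 and 0 with both, while the list medians with both blocks were -0.14, -0.13 and -0.08.

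Of 14 glucocorticoid-responsive genes 3 rose, the same number when adjusted over the list alone: Fkbp5 (1.60-fold, adjusted p = 0.026), Nfkbia (1.20-fold) and Klf9 (1.14-fold). The list had an adjusted p of 1.8e-05, but adjusted p = 0.28 with an estimated correlation. With the run block 2 of the 3 were called and with run and lot blocks none, where Fkbp5 had 1.01, Nfkbia 0.28 and Klf9 0.25 (adjusted p = 0.16, 0.22 and 0.067). The astrocyte list passed (adjusted p = 0.029, and adjusted p = 0.53 with an estimated correlation), with the glutamate transporters Slc1a3 and Slc1a2 higher by 0.24 ± 0.05 and 0.16 ± 0.03 SE and the neurotensin receptor Ntsr2 lower by -0.23 ± 0.06, while its median of 0.02 turned to -0.005 after each array was centred on its median. The interneuron list passed as well (adjusted p = 0.029, and adjusted p = 0.32 with an estimated correlation), but not with the mean over probe sets per gene (adjusted p = 0.11) nor with run and lot blocks (adjusted p = 0.28). Its cannabinoid receptor gene Cnr1 rose by 0.17 ± 0.04 SE, and the calcium buffer gene Pvalb fell by 0.25. The astrocyte and interneuron lists had 2 higher with 1 lower and 1 higher with 1 lower, over all genes and when adjusted over the list alone.

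The largest prefrontal rises outside the interval, besides the 2 microRNA transcripts Lncppara and A330023F24Rik, were in Sntb2, a syntrophin of the dystrophin complex (3.52-fold, log2 difference 1.82 ± 0.31 SE, adjusted p = 0.00085), Tmem178b (2.51-fold), the transcription factor Sp4 (2.22-fold), Creg2 (2.14-fold), the nuclear noncoding RNA Malat1 (2.09-fold), Gprin3 (1.96-fold), Endod1 (1.67-fold) and Clec16a, a regulator of mitophagy (1.65-fold, adjusted p = 9.7e-07). Sntb2, Tmem178b, Sp4 and Creg2 were above the wild-type mean in 9 of 10 Df(16)A/+ arrays. The largest fitted falls were in Ecrg4 (log2 difference -1.62 ± 0.38 SE, with a Df(16)A/+ mean of 3.65 that lies under the filter value of 4, so that the size is uncertain), Npas4 (-1.01 ± 0.21), Fos (-0.90 ± 0.27), Slc47a1 (54.2%), the interferon gamma receptor subunit Ifngr2 (55.5%), Pcp4l1 (56.2%), Slc26a7 (57.4%), Ogn (58.3%), the iron exporter Slc40a1 (61.6%) and Shld1 (61.7%). Ogn belonged to the mural and meningeal marker list, of which 2 of 15 genes fell and the list did not pass (adjusted p = 0.23).

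The prefrontal arrays were not balanced over batches. Run 4 held 7 wild-type and 5 Df(16)A/+ arrays, run 3 held 3 and 1, and run 5 held 4 Df(16)A/+ arrays only, while 6 wild-type arrays came from a chip lot with no Df(16)A/+ array. The count of called probe sets was 2003 with the run as a block, 986 with the chip lot, 455 with both (299 higher and 156 lower), 512 within run 4 and 329 within lot 1. With both blocks 7 of the 9 primary microRNA transcripts were still called and so was Emc10 (0.54, adjusted p = 0.0074), whereas 55 of 94 named prefrontal genes no longer were, the 10 largest falls and the named synaptic genes among them. In run 4 that fit set the Df(16)A/+ arrays against wild-type replicate 10 alone, the lowest wild-type array for the primary microRNA list. With both blocks Fos had -1.24, Npas4 -0.85, Ecrg4 -1.37, Sntb2 1.47, Sp4 1.04, Creg2 0.98, Gprin3 0.81 and Gsk3b 0.26, and the synaptic genes Dlg4 0.38, Dlgap2 0.30, Slc17a7 0.27 and Gria1 0.22. The other large falls had -0.87 (Slc47a1), -0.86 (Ifngr2), -0.99 (Pcp4l1), -0.83 (Slc26a7), -0.56 (Ogn), -0.93 (Slc40a1) and -0.52 (Shld1).

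**Figure D2:**
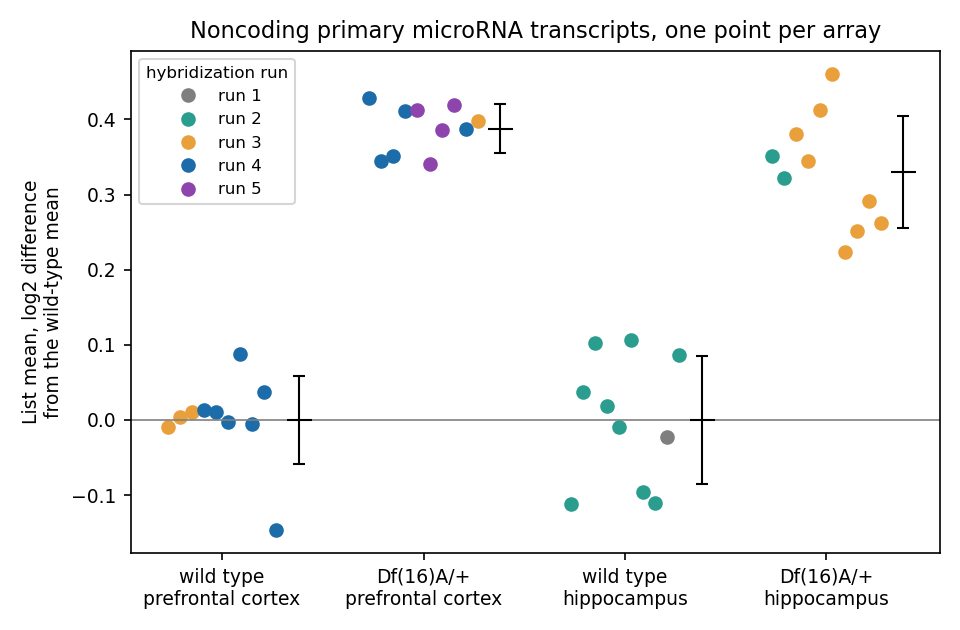
Mean log2 signal of the noncoding primary microRNA transcripts in each array (y axis, relative to the wild-type mean of its region) for the 4 groups (x axis), coloured by hybridization run, with the group mean and SD in black. The Df(16)A/+ arrays lie between 0.34 and 0.43 in the prefrontal cortex and between 0.22 and 0.46 in the hippocampus, above all wild-type arrays of the same region.

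The same question was asked in the hippocampus. The primary microRNA transcripts were again higher: 6 of 15 measured rose and none fell in Df(16)A/+ mice (9 rose when adjusted over the list alone), among them Lncppara (1.93-fold), A330023F24Rik (1.76-fold) and C130071C03Rik (0.58 on the log2 scale). Emc10 rose 1.38-fold, from 11.12 ± 0.14 to 11.58 ± 0.09 (SD, log2). Clec16a rose 2.09-fold, the NMDA receptor subunit gene Grin2a 2.01-fold and Cntnap1, a protein of the axon-glia junction, 1.95-fold. Genotype and hybridization run overlapped strongly in this region, and with the run as a block Clec16a had 0.89, Grin2a 0.78 and Cntnap1 0.29 (adjusted p = 0.13, 0.85 and 0.93).

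In the hippocampus limma called 1369 of 21153 probe sets (6.5%), 1098 higher and 271 lower, of which 1342 lay outside the interval genes. The share of higher calls depended on the scaling, 80.2% as deposited, 63.4% after quantile normalization and 93.8% after median centring. The median size was 0.33 on the log2 scale, 192 differences reached 1.5-fold (160 higher) and 5160 had an unadjusted p under 0.05. With 1 probe set per gene 228 genes were higher and 168 lower. Run 2 held 9 wild-type and 2 Df(16)A/+ arrays, run 3 held 8 Df(16)A/+ arrays only, and run 1 held 1 wild-type array. With the run as a block 33 probe sets were called (11 higher and 22 lower), within run 2 alone 31, with the chip lot as a block 436 and within lot 1 397.

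The primary microRNA list passed in the hippocampus (adjusted p = 1.2e-08, and 0.0022 with an estimated correlation) and also with the run as a block (adjusted p = 5.5e-11). A330023F24Rik, C130071C03Rik, Lncppara and Mir22hg were called with and without the run block, with differences of 0.82, 0.58, 0.95 and 0.48 without it and 0.83, 0.68, 0.98 and 0.70 with it. With run and lot as blocks Lncppara kept its 0.98 but was not called (adjusted p = 0.060). Dleu2 (0.47 without and 0.69 with the block) and Mir124a-1hg (0.39 and 0.24) were called without the block only (adjusted p = 0.41 and 1.00 with it). The list mean was 0.33 ± 0.07 (SD) above wild type, 0.34 in the 2 Df(16)A/+ arrays of run 2 and 0.33 in the 8 of run 3. Of the 3 genes studied downstream of this deletion Emc10 passed (0.47 ± 0.06 SE, adjusted p = 2.2e-05), and Gsk3b (0.28 ± 0.17) and Atp2a2 (0.13 ± 0.06) did not (Emc10 and 1 more rose when adjusted over the list alone). That list passed (adjusted p = 0.0026) but not with an estimated correlation (adjusted p = 0.20) nor with the run block (adjusted p = 0.77), where Emc10 had 0.39 (adjusted p = 0.15).

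Of 42 genes of the glutamatergic synapse 6 rose and none fell (7 and 1 when adjusted over the list alone). Grin2a had a difference of 1.01 ± 0.21 SE, Dlg4 of 0.72 ± 0.13, Nrxn2, a presynaptic adhesion protein, of 0.40 ± 0.10 and Slc17a7 of 0.38 ± 0.06. The list passed (adjusted p = 0.0018) but had adjusted p = 0.64 with an estimated correlation and 0.77 in the opposite direction with the run block. Its mean was 0.15 above wild type in the 8 Df(16)A/+ arrays of run 3 and -0.01 in the 2 of run 2. Cytosolic ribosomal proteins fell in 4 of 45 cases (10 when adjusted over the list alone), with Rpl37 at 81.9% of wild type. Their list passed (adjusted p = 1.2e-08, but adjusted p = 0.26 with an estimated correlation) and also with the run block (adjusted p = 0.0020), where however none of its genes was called, the median went from -0.08 to -0.04 and Rpl37 from -0.29 to -0.07. Of 76 genes of oxidative phosphorylation 3 fell (1 when adjusted over the list alone). That list had adjusted p = 0.028 and, with an estimated correlation, adjusted p = 0.77, and its median of -0.03 turned to 0.02 after median centring. With the run block it passed by camera (adjusted p = 0.0031, median -0.04), where none of its genes was called.

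Among glial and vascular markers, 1 of 20 oligodendrocyte genes fell, the myelin-associated Opalin (71.2% of wild type), and 2 of 20 when adjusted over the list alone. The list passed (adjusted p = 0.0041, but adjusted p = 0.77 with an estimated correlation). By camera with the preset correlation it also passed with the run block (adjusted p = 0.00019), the lot block (adjusted p = 0.00037) and both (adjusted p = 0.00031). With the run block its median was -0.12 and none of its genes was called. Of 16 mural and meningeal genes Pdgfrb, the pericyte receptor, fell to 72.4% (4 fell when adjusted over the list alone). The list passed (adjusted p = 0.0018, but adjusted p = 0.64 with an estimated correlation), and with the run block its adjusted p was 0.96. Of 14 glucocorticoid-responsive genes none was called by limma in either count, although the list passed (median 0.14, adjusted p = 0.0029, but adjusted p = 0.66 with an estimated correlation and 0.54 in the opposite direction with the run block).

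The largest hippocampal rises outside the interval were, besides those above, in Malat1 (1.82-fold), the calcium channel gene Trpc5 (1.74-fold), Dlg4 (1.65-fold), Creg2 (1.64-fold) and Smc6, part of a chromosome maintenance complex (1.54-fold). The largest falls were in Ninl (64.9% of wild type), Trim59 (65.4%), Nipal4 (68.6%), Gt(ROSA)26Sor (68.7%), Opalin, Cdc42ep2 (71.6%), Zfp949 (71.9%), Rffl (72.1%), Pdgfrb and Cdc42ep1 (72.7%). Of these rises and falls, only the microRNA transcripts Lncppara and A330023F24Rik were still called with the run block. Within run 2, Malat1 had a difference of -0.34, Creg2 of -0.14, Smc6 of -0.17 and Ninl of 0.12, opposite to their differences over all arrays, and Clec16a had 0.89 with the run block (adjusted p = 0.13) and the same difference with run and lot as blocks, where it was called (adjusted p = 0.016). In the prefrontal cortex Clec16a had 0.92 with both blocks (adjusted p = 0.00050).

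**Figure D3:**
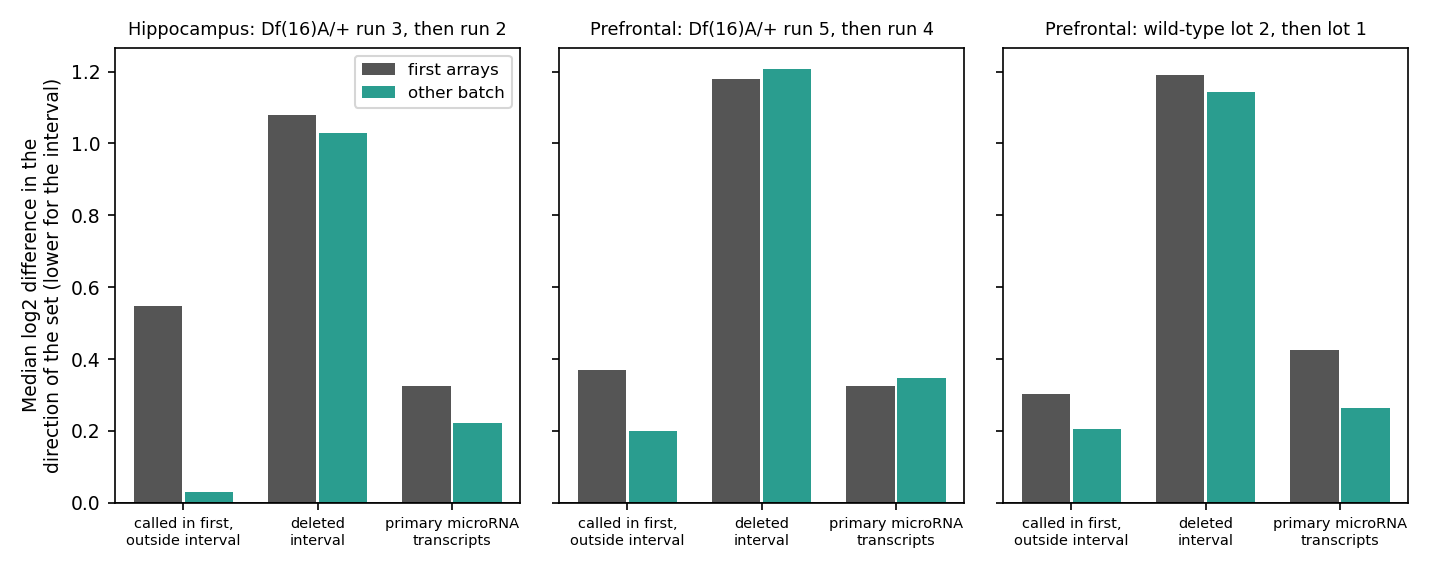
Median log2 difference in arrays of 1 batch (grey) and in other arrays of another batch (green) for 3 sets of probe sets (x axis), signed so that each set's direction in the first arrays is positive and lower interval genes are positive. Hippocampal probe sets called with the run 3 arrays had a median of 0.55 there and 0.03 with the run 2 arrays, whereas the deleted interval had 1.08 and 1.03. The called sets were chosen and signed by the first arrays, which raises their first median. The interval and primary microRNA lists were fixed beforehand.

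Whether the genotype effect differed between the regions was tested as an interaction over all 40 arrays. Of 22586 probe sets 572 were called, 509 with a higher effect in the hippocampus and 63 with a lower one (4693 at an unadjusted p under 0.05). The split depended on the scaling, with 141 higher and 53 lower after quantile normalization and 1010 and 25 after median centring. None of the 19 interval genes was among the 332 genes called. Of the 10 genes with the smallest adjusted p, 9 were lower in the prefrontal cortex and not called in the hippocampus. Get3, which inserts tail-anchored membrane proteins, had -0.28 in the prefrontal cortex and 0.07 in the hippocampus (difference 0.35 ± 0.06 SE, adjusted p = 0.0035). Ufsp2, a protease for the modifier UFM1, had -0.22 and 0.13 (difference 0.35 ± 0.06, adjusted p = 0.0035). Spsb3 had -0.36 and 0.08, Cops6, a subunit of the COP9 signalosome, -0.28 and 0.03, Arhgap15 -0.19 and 0.16, Gskip -0.19 and 0.15, Txnl4b -0.36 and 0.21, Ifngr2 -0.85 and 0.26, and Tmem126a, a mitochondrial membrane protein, -0.24 and -0.02. Olfml2b, which the filter removed in the prefrontal cortex, was higher in the hippocampus (0.46, interaction 0.44 ± 0.07 SE). With the run as a block 15 probe sets were called in the interaction and none of these 10 genes, and with the chip lot 1 probe set.

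How far the regions shared the effect was compared over 20306 probe sets tested in both. Both regions called 493 in the same direction, 395 higher and 98 lower, against 63.7 and 34.2 for independent lists, and 9 in opposite directions. Across probe sets outside the interval the log2 differences correlated with r = 0.47, where probe sets are not independent replicates. In 100 random regroupings within each region the largest absolute r was 0.43 and the median 0.12, and the covariance was 0.0131 against at most 0.0035. With the run block 26 probe sets were shared, 8 of them outside the named interval genes, and r was 0.10. The 5 named genes among the 8 were higher in both regions: A330023F24Rik, C130071C03Rik, Lncppara, Mir22hg and Aopep, an aminopeptidase gene whose span holds Mir23b, Mir24-1 and Mir27b. Aopep, named here after its values were seen, had 0.91 in the prefrontal cortex and 0.73 in the hippocampus with the run block (adjusted p = 2.9e-05 and 0.024). These values came from a probe set other than the one with the highest mean, which had 0.58 and 0.32 (adjusted p = 0.00030 and 0.85). The other 3 probe sets were not assigned to a gene here and were lower in both regions.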

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

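Of the tests in this part, the RNA integrity test and the fits with the hybridization run, or run and lot together, as blocks were chosen only after the result was seen.

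In 314 groups of 10 arrays (a named gene or a list mean in 1 genotype and region), 23 held an array far from the others, by the gap to its nearest neighbour as a share of the group's range, with Dixon's 95% critical value for 10 arrays as the limit. Chance sets about 1 in 20 groups apart. Whether 23 exceeds that was not tested, and some of these groups share an array, such as replicate 6 in wild-type hippocampus with 3. In wild-type prefrontal cortex the lowest arrays were replicate 10 for C130071C03Rik (0.52) and for the mean of the primary microRNA list (0.583), and replicate 3 for Nfkbia (0.541) and Fkbp5 (0.469). The highest were replicate 6 for Thap7 (0.588), replicate 1 for Lingo1 (0.486) and replicate 7 for the microglial genes Tyrobp (0.674) and C1qa (0.663). In Df(16)A/+ prefrontal cortex the lowest arrays were replicate 4 for Mrpl57 (0.51), 10 for Rpl22l1 (0.529), 3 for Rps4l (0.485), 5 for Nfkbia (0.477), 7 for Car15 (0.485) and 6 for Thap7 (0.508). In wild-type hippocampus, replicate 6 was highest for C1qb (0.606) and Laptm5 (0.734), both microglial, and for Tango2 (0.503), and replicate 3 was lowest for Prodh (0.508) and highest for Reln (0.501). In Df(16)A/+ hippocampus, replicate 10 was lowest for Rtn4r (0.467) and replicate 1 for Gsk3b (0.491), and replicate 7 was highest for Txnrd2 (0.576) and replicate 3 for Zfp949 (0.476).

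The interaction called a difference of the genotype effect between the regions for 25 named genes. The first 10 listed here were named for their small adjusted p in this same test. The hippocampal effect was higher by 0.348 in Get3, 0.442 in Olfml2b, 0.349 in Ufsp2, 0.435 in Spsb3, 0.344 in Arhgap15, 0.344 in Gskip, 0.32 in Cops6, 0.571 in Txnl4b, 1.108 in Ifngr2 and 0.225 in Tmem126a. It was also higher by 0.235 in Atp5c1, 0.227 in Ndufs3, 0.2 in Mrps12, 0.425 in Mrps11, 0.237 in Ap2m1, 0.562 in Maoa, 0.288 in Omg, 0.436 in Tle4, 0.347 in Rspo1, 0.311 in Tdo2 and 0.289 in Npy. The interaction was negative for Sntb2 (-1.436), Mir9-3hg (-0.293), Slc1a3 (-0.353) and Nipal4 (-0.636). Over all probe sets chance was excluded for the interaction (572 called, 1 of 100 regroupings as large, highest other 1), but with the run as a block 15 were called. With the chip lot as a block 1 was called, and none of those 10 genes kept its call with either block. For the 493 probe sets shared between regions the regroupings could not decide. None of the 99 other prefrontal splits called a probe set, which fixed their shared count at 0. The correlation outside the interval was 0.47, against an absolute r of at most 0.428 in the regroupings. These regroupings did not keep the overlap of genotype with run.

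The hippocampal difference outside the interval (1342 probe sets) went with the hybridization run. Chance was excluded for all 1369 called probe sets (1 of 100 splits as large, the real one, highest other 1), but these splits did not keep the overlap of genotype with run. A split of the same arrays by run, run 3 against runs 1 and 2, called 4700 probe sets, 1269 of them among the 1369. All 8 arrays of run 3 were Df(16)A/+, so that split overlaps with genotype as well. Inside Df(16)A/+ arrays the change from run 2 to run 3 correlated with the genotype effect at r = 0.657. That comparison shares its run 3 arrays with the genotype effect. In separate arrays, 507 probe sets called with run 3 mutants had a median of 0.55 there and 0.03 with run 2 mutants. They were chosen and signed by the first arrays, which raises the first median, so part of the fall follows from that choice. A run effect is a candidate explanation for most of the difference. The beta-actin covariate left 43.5% of the calls, which decides neither for nor against RNA integrity. A genotype effect in some of these genes stays open, since 8 of 10 mutants were in a run with no wild type and the run block left 2 mutants to compare.

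The prefrontal difference outside the interval (3972 probe sets) was weighed next, and chance was excluded for all 4000 called probe sets (1 of 100 splits, highest other 0). These splits did not keep the overlap of genotype with run and lot. Against the chip lot as the whole cause, 972 probe sets called with lot 2 wild types had a median of 0.30 there and 0.20 in other mutants with lot 1 wild types, the mutants' own lot, 96.4% with the same sign. The lot effect inside wild type correlated with the genotype effect at r = 0.078, but that contrast mixes lot with run, since 3 of its 4 lot 1 arrays were in run 3 and all 6 of lot 2 in run 4. For the run, r was 0.367 inside Df(16)A/+ arrays, and the run cannot be told apart from genotype for part of the difference, since run 5 held mutants alone. In separate arrays, 1284 probe sets called with run 5 mutants had a median of 0.37 there and 0.20 with run 4 mutants, 97.1% with the same sign. The 972 and the 1284 probe sets were chosen and signed by their first arrays, which raises the first median. The lower second median therefore does not measure a batch effect alone. A genotype effect of smaller size stays open as a hypothesis.

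The primary microRNA transcripts were higher in both regions. Run and lot were argued against as the whole cause, since with both as blocks the list median was 0.363 in the prefrontal cortex (7 of 9 genes still called) and 0.24 in the hippocampus (3 of 6), and so was a general rise of noncoding RNA, since other long noncoding RNAs had medians -0.077 and -0.147 times those that hold a microRNA. In run 4 the prefrontal fit with both blocks set 5 mutants against wild-type replicate 10 alone, the lowest for this list (-0.147), so its size is uncertain. Its other wild-type arrays were the 3 of run 3, with 1 mutant. In separate arrays the prefrontal list median was 0.326 with run 5 mutants and 0.348 with run 4 mutants. It was 0.426 with lot 2 wild types and 0.263 with lot 1 wild types. The hippocampal list median was 0.324 with run 3 mutants and 0.221 with the 2 mutants of run 2. The hippocampal fit with both blocks rested on those 2 mutants, which alone shared a run with wild type, so its size is uncertain too. Long noncoding RNAs that hold a microRNA lay at percentile 100 of matched random lists in both regions, but 12 of these 13 were in the list already, so this mostly restates its rise. Slower processing of primary transcripts with less Dgcr8 may explain the rise, a hypothesis whose processing step was not measured here.

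For the interval genes chance was excluded in both regions (19 and 18 genes called, 1 of 100 splits as large, highest other 0). It was not excluded for the number of gene lists that passed: 11 of 100 splits gave at least the 10 lists of the prefrontal cortex (highest other 14), and 19 of 100 at least the 9 of the hippocampus (highest other 13). For single prefrontal lists, 16 of 100 splits gave as small a camera p for astrocytes, 14 for cytosolic ribosomal proteins and 12 for interneurons. There were 9 for glucocorticoid-responsive genes and 2 for oxidative phosphorylation. Hippocampal numbers were 26 for mural, 23 for glucocorticoid, 22 for oligodendrocyte and 20 for oxidative phosphorylation genes. Cytosolic ribosomal proteins had 4 and the glutamatergic synapse 2. For the other lists that passed, only the real split did.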

How the results depend on the processing

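The run block, run and lot blocks together, single runs or lots and the actin covariate were tests chosen only after the result was seen. Where not stated otherwise, the cause was not tested.

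The prefrontal count of 4000 became 986 with the chip lot as a block, 2506 with the fluidics station, 2003 with the run, 455 with run and lot, 1 within run 3 (1 mutant array, assumed to vary like the others, so that this count speaks neither for nor against a run effect), 512 within run 4 and 329 within lot 1, the last 3 with fewer arrays, and 232 at 1.5-fold or more, a stricter threshold. Under no filter, a filter above 6, quantile normalization, centring, trend, weights, Welch's test, all 40 arrays, the day block and the actin covariate it was 3124 to 4929. The interval median of -1.229 became -1.158 with the lot block and within lot 1, -1.149 with run and lot and -1.069 within run 3, where 0 of 19 genes were called with 1 mutant array.

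The hippocampal count of 1369 became 812 without a filter (more probe sets tested), 2335 with array weights, 806 by Welch's test, 2974 with all 40 arrays in 1 fit, 436 with the lot block, 33 with the run block, 38 with run and lot, 31 within run 2, 397 within lot 1, 633 with the actin covariate and 192 at 1.5-fold or more. In simulated data with as many changed probe sets the run block alone lowered the calls from between 1124 and 1161 to between 233 and 248. The real arrays kept 33, fewer than any of these simulations. How much of the real fall came from lost power was not settled by them.

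The interaction count of 572 became 298 without a filter, 194 with quantile normalization, 1035 with centring, 1161 with weights, 363 by Welch's test, 1 with the lot block, 379 with the station block and 15 with the run block. The shared count of 493 became 287 without a filter, 26 with the run block and 27 with run and lot.

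As a replicate block, the number in the titles gave 3311 prefrontal and 1602 hippocampal calls and interval medians of -1.229 and -1.056. In the genotype by region interaction, the animal by number gave 678 as a random and 231 as a fixed replicate block. The numbers did not pair the arrays: same-number correlations ran from -0.266 to 0.342, and the own number was the best match for 1 of 10 in each pair of groups (consensus correlation 0.023).

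Some hippocampal directions reversed. With the run block, and with run and lot, the adjusted p in the opposite direction was 0.765851 and 0.976911 for the glutamatergic list, 0.539387 and 0.617736 for the glucocorticoid list, 0.0209888 and 0.0144959 for the endothelial list and 0.958741 and 0.909024 for the mural list. With the run block, with run and lot and within run 2 alike, the log2 difference was -0.342 for Malat1, -0.142 for Creg2, -0.17 for Smc6, 0.124 for Ninl, -0.091 for Atp2a2, -0.427 for Gsk3b, -0.019 for Nrxn2 and 0.039 for Laptm5. Within prefrontal run 3, Ntsr2 had 0.087 and C1qa 0.021. Of 94 named prefrontal genes, 79 kept their direction and side of the threshold with the run block, 60 with the lot block and 39 with both, and of 59 hippocampal genes 19 did with the run block.

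In leave-one-out fits the prefrontal count ran from 3244 to 4704 and its interval median from -1.242 to -1.201, the hippocampal count from 785 to 2316 and its median from -1.09 to -1.032, and the interaction from 182 to 1286. In the genotype comparison, hippocampus counts moved by over 1.5 times without Df(16)A/+ replicate 1 (2190), 2 (2316), 3 (801) or 10 (898), or wild-type replicate 2 (785), 4 (834), 5 (906) or 10 (792). The genotype by region interaction did so without prefrontal wild-type replicate 4 (353), 6 (365), 8 (348), 9 (249) or 10 (324), prefrontal Df(16)A/+ 4 (182), 5 (290), 7 (354) or 9 (349), hippocampal wild-type 2 (244), 4 (322), 5 (306) or 10 (308), or hippocampal Df(16)A/+ 1 (1286), 2 (1141), 3 (208), 5 (241) or 8 (950).

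The region comparison in wild type and the hippocampal day block were not run. Signals near background limit the arrays: probe sets not above 4 in at least 10 arrays were not tested, which left 6 interval genes with a probe set out.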

Other observations

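The run block, and run and lot together, were tests chosen only after the result was seen.

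Of 20 flanking genes on chromosome 16, 7 fell in the prefrontal cortex (8 when adjusted over the list alone), among them Car15 (-0.63 ± 0.12 SE), Alg3 (-0.41 ± 0.10), Thap7 (-0.23 ± 0.06) and Ap2m1 (-0.20 ± 0.04), but the list did not pass (adjusted p = 0.085), nor in the hippocampus (median 0.03, adjusted p = 0.70). The prefrontal number of lower genes was 3 with the run block and 1 with the lot block or both. Of 25 activity-regulated genes 5 fell in the prefrontal cortex (7 when adjusted over the list alone), with Btg2 at -0.58 ± 0.15 SE and Ier2 at -0.55 ± 0.13 beside Fos and Npas4 (list adjusted p = 0.28). With the run block 5 were lower and with the lot block or both 0, but with both blocks the list passed (adjusted p = 0.022, median -0.26 against -0.21). In the hippocampus Nptx2, which encodes a pentraxin, rose by 0.31 ± 0.06 (list adjusted p = 0.70). Lingo1, a partner of the Nogo receptor, rose in the prefrontal cortex by 0.42 ± 0.07 SE (0.41 with the run block). In the hippocampus its 0.38 ± 0.07 became 0.02 with the run block (adjusted p = 1.00). Omg, a ligand of that receptor, fell in the prefrontal cortex (-0.24 ± 0.05). The axon growth list did not pass in either region (adjusted p = 0.17 and 0.19).

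Several prefrontal marker genes were lower while their lists did not pass, and with run and lot as blocks no gene of the microglial, oligodendrocyte, endothelial, mural or cortical layer lists was called (with the run block alone 0, 2, 1, 0 and 2). Their list medians were -0.15, -0.10, -0.19, -0.26 and -0.07 without blocks and -0.09, -0.11, -0.25, -0.22 and -0.05 with both, so the lost calls do not show that the falls went. Microglial Tyrobp fell by 0.41, C1qa by 0.29 and Gpr34 by 0.23 (list adjusted p = 0.22), oligodendrocyte Opalin by 0.45 (adjusted p = 0.27), endothelial Slco1a4 by 0.58 and Itm2a by 0.43 (adjusted p = 0.39), pericyte Pdgfrb by 0.35, and the cortical layer genes Tle4 by 0.47 and Rspo1 by 0.38 (adjusted p = 0.51). Ppp1r1b, which encodes DARPP-32, rose by 0.45 ± 0.06 SE, and Maoa, which degrades monoamines, fell by 0.35 (monoamine list adjusted p = 0.23). With both blocks Ppp1r1b was called (0.43) and Maoa was not (-0.32). Gad1, for GABA synthesis, rose by 0.11 ± 0.04 and the receptor subunit Gabrd fell by 0.22 (GABA list adjusted p = 0.32), neither called with both blocks (0.12 and -0.20). In the hippocampus Npy and Reln rose by 0.26 ± 0.06 and 0.26 ± 0.07 SE (interneuron list adjusted p = 0.14), and the dentate genes Tdo2 and Prox1 by 0.32 ± 0.08 and 0.27 ± 0.08 (adjusted p = 0.64). The dentate list passed upward with the run block (adjusted p = 0.022, median 0.16) and with run and lot (adjusted p = 0.0057), and the interneuron list with the lot block (adjusted p = 0.045). Microglial C1qb and Laptm5 fell by 0.43 and 0.33 (adjusted p = 0.17), Cryab fell by 0.40 (heat shock list adjusted p = 0.84) and Tnrc6c by 0.21 (microRNA pathway adjusted p = 0.24). None of the hippocampal genes named in this part was called with the run block, where C1qb had -0.05, Laptm5 0.04, Cryab -0.16, Tnrc6c -0.05, Npy 0.21, Reln 0.22, Tdo2 0.32, Prox1 0.14 and Nptx2 0.24.

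By camera the other lists did not pass without blocks and with 1 probe set per gene. By fry, prefrontal cell cycle, flanking and cortical layer genes passed downward (adjusted p = 0.027, 0.0022 and 0.00036). The prefrontal glucocorticoid, astrocyte and interneuron lists did not pass by fry (adjusted p = 0.065, 0.58 and 0.30). In the hippocampus fry passed only the interval, primary microRNA, downstream and cytosolic ribosomal lists. Values that follow are from camera. Prefrontal heat shock genes passed upward with run and lot blocks (adjusted p = 0.047), and hippocampal endothelial genes passed downward with the lot block (adjusted p = 0.0056) and upward with the run block (adjusted p = 0.021). With the mean over probe sets, choroid plexus passed downward in the hippocampus (adjusted p = 0.044), and protein-coding microRNA hosts passed upward in both regions (adjusted p = 0.036 and 0.048), although with 1 probe set per gene none of their 45 genes was higher and 4 and 1 were lower. With an estimated correlation the hosts had adjusted p = 0.53 and 0.80, and their hippocampal direction turned with the run block. In the prefrontal cortex the adjusted p was 0.098 for protein-coding microRNA hosts, 0.90 for heat shock, 0.78 for cell cycle, 0.40 for oligodendrocyte precursors, choroid plexus and striatum, 0.23 for thalamus and for mural and meningeal genes, 0.82 for dentate gyrus, 0.91 for CA fields and 0.51 for immature neurons. In the hippocampus it was 0.23 for microRNA hosts, 0.75 for GABAergic transmission, 0.79 for monoamine signalling, 0.45 for mitochondrial ribosomal proteins, 0.64 for cell cycle, 0.19 for oligodendrocyte precursors, 0.56 for astrocytes, 0.12 for endothelium, 0.14 for choroid plexus, 0.92 for striatum, 1.00 for thalamus and for CA fields, 0.24 for cortical layers and 0.35 for immature neurons.

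The choice of probe set mattered for the counts. In 4858 hippocampal genes with several tested probe sets, 2.1% of the probe sets with the highest mean were higher in Df(16)A/+ mice, against 10.01% of the 7996 other probe sets. In 4965 prefrontal genes the shares were 4.09% and 9.82%. Lower calls were 1.52% against 0.74% in the hippocampus, a gap that was 3.42% against 1.68% after quantile normalization and absent after median centring (0.25% and 0.24%), and 14.4% against 8.82% in the prefrontal cortex. With the run as a block the hippocampal shares were 0.02% and 0.05% higher and 0% and 0.01% lower, and the prefrontal ones 2.34% and 4.44% higher and 7.07% and 4.22% lower. The beta-actin 3' and 5' difference was -0.09 for Df(16)A/+ minus wild type in the hippocampus (permutation p = 0.147) and -0.01 in the prefrontal cortex (permutation p = 0.756).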
